A study of Homo sapiens with 6 samples.

How the data were processed

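Gene expression was measured on 6 Clariom S human arrays, which hold 1 probe set per transcript cluster. The cells were human myotubes, multinucleate muscle cells made in culture from myoblasts with 2% horse serum, per the labels' protocols. They were transfected with siRNA through a lipid reagent once they had become myotubes. A scrambled siRNA (siScramble) was used for 3 samples and an siRNA against COPS2 (siCOPS2) for the other 3. In each group the samples carry the letters A, B and C. The labels do not say what the letters mark, nor that the samples came from separate cultures or donors. No p-value therefore reaches beyond these 6 samples. Those of single probe sets rest only on the spread between the 6, shared in part across probe sets, and that spread may be technical.

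The values used are the log2 expression values deposited by the authors, 1 column per array. RMA, which corrects background, normalizes between arrays and summarizes probes, and limma are named in the submitters' processing notes without versions, and the order and settings of the steps are not given in the sources used here. The log2 scale was taken from the values themselves. All columns were mapped to a sample. The arrays had been put on nearly 1 distribution before deposit: the medians of the tested probe sets were 5.50, 5.50 and 5.47 for siScramble A, B and C and 5.46, 5.50 and 5.46 for siCOPS2 A, B and C. A difference shared by most genes of an array would have been removed by that step. Scanner values were not analysed here.

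Of 27189 deposited probe sets, 21448 transcript clusters were tested, and 5741 control or unnamed probe sets were left out. The platform annotation gave exactly 1 gene symbol for 17709 of the tested probe sets, several for 0 and none for 3739, and the symbols were looked up through gene identifiers in the RefSeq annotation of GRCh38.p14, where 17709 matched and 0 had a newer name. The 17687 symbols include 20 found on over 1 probe set; the probe set with the highest mean over all arrays then stood for the gene. No coordinates are printed, because the genome build of the array annotation is not given in the sources used here. Probe sets of near-identical genes, such as the myosin heavy chains and the trypsinogens, can take up each other's transcripts, so MYH8 and PRSS3 are uncertain in that respect.

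Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default priors, two-sided), siCOPS2 minus siScramble, with Benjamini-Hochberg adjustment over the 21448 probe sets and a threshold of 0.05. The errors of log2 fold changes are limma's standard errors, and intervals are at the 95% level. The number of arrays, 3 per group, limits the precision: the median standard error of a log2 fold change was 0.17, and the smallest two-sided p of an exact permutation test of 3 against 3 is 0.1. In the mean over all arrays, 73.3% of the tested probe sets lay above 4.16 log2 units, the 95th percentile of the 612 negative control probe sets averaged over arrays. Data were simulated for this comparison from these means and from limma's variances, which are pulled towards a common value (21448 probe sets, 200 of them changed, 20 simulations). There log2 changes of 0.5, 1, 2 and 3 were recovered in 13.4%, 94.2%, 100% and 100% of cases, and 6.67% of the calls were false. The simulation draws every probe set independently and leaves out any structure shared between arrays. Its noise is smaller than the observed spread for the most variable probe sets, and with 200 changes the adjustment is more lenient than with few. In the real data COPS2, at a log2 fold change of -2.15, had a limma adjusted p of 0.080, so these rates do not carry over to it.

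Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists, which hold 756 measured genes. camera asks whether the genes of a list differ more in one direction than other genes. With the preset correlation its p-value rests on the spread across genes, taken as nearly independent, more than on the spread between arrays. It was run again with the correlation estimated for each list, and fry was run as a test of each list on its own. In a simulation of 17687 genes camera found a list of 30 genes shifted by 0.3 in 20 of 20 cases and an unshifted list in 0. A list counted as found there at an unadjusted p under 0.05, which is more lenient than the adjustment over 32 lists. Genes were independent there too. Single members were counted over all probe sets and adjusted over the list alone. A list's score on an array is the mean over its members of the value minus that gene's mean over the 6 arrays.

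The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took COPS2 first. It then took genes with 1 symbol past the threshold, with the higher group mean above the median of all tested values (5.48) and no overlap between the groups, up to 12 in each direction by size. Where fewer passed, the genes of smallest p that met the other criteria filled each direction up to 6, given as not past the threshold. Of each list described it took up to 4 members of smallest p. Alternatives were the replicate letter as a block or a random effect, other variance models, array weights, other normalizations, filters and thresholds, and leaving out each of the 6 arrays in turn. No batch is given in the labels, and no array was a copy of another.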

Results

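The study asks what happens to gene expression in human myotubes when COPS2 is knocked down; its title places COPS2 (also TRIP15 or ALIEN) in skeletal muscle in cancer and exercise training. Transcript levels were measured on 3 arrays of myotubes given a scrambled siRNA and 3 given an siRNA against COPS2. Pairwise correlations across probe sets lay between 0.975 and 0.988. These are correlations across genes, which are not independent replicates. siScramble B stood furthest from the rest, with a mean correlation of 0.979 to the other arrays against 0.983 to 0.985 for the other arrays, and siScramble B and siScramble C made the least similar pair.

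COPS2, a subunit of the COP9 signalosome that removes NEDD8 from cullins, was lower in all 3 siCOPS2 arrays than in any siScramble array. Its probe set averaged 5.19 ± 0.13 log2 units after siCOPS2 (SD, n = 3) and 7.34 ± 0.77 after siScramble (SD, n = 3). The log2 fold change of -2.15 ± 0.29 (SE) leaves 22.6% of the control signal, with a 95% interval from 14.5% to 35.1%. This error uses limma's variance, pulled towards a common value, so the interval is narrower than COPS2's own spread would give. With ordinary variance the adjusted p over all probe sets was 0.889. COPS2 fell when adjusted over the list of COP9 subunits alone (limma adjusted p = 8.14e-05), and over all probe sets the adjusted p was 0.080. The siScramble arrays differed widely in COPS2, at 7.16, 8.18 and 6.67 log2 units for A, B and C. With 1 array left out the adjusted p over all probe sets was 0.021 without siScramble B and 0.013 without siScramble C, and 0.153 to 0.726 without any of the others.

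Beyond COPS2, the 2 genes with the clearest separation were both lower after siCOPS2. AGPS, a peroxisomal enzyme of ether lipid synthesis, averaged 5.09 ± 0.50 against 6.98 ± 0.28 log2 units (SD, n = 3 per group), a log2 fold change of -1.89 ± 0.24. CKAP2, a protein of the mitotic spindle, lay at 4.76, 5.11 and 5.14 log2 units in siCOPS2 A, B and C and at 6.97, 7.13 and 6.08 in siScramble A, B and C, a log2 fold change of -1.72 ± 0.24. Neither passed the threshold over all probe sets, with limma adjusted p of 0.067 for AGPS, the smallest of any probe set, and 0.080 for CKAP2. With 1 array left out the adjusted p ran from 0.051 to 0.60 for AGPS and from 0.0047 to 0.746 for CKAP2, which passed without siScramble C only.

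The other genes taken by rule were further from the threshold. Among those higher after siCOPS2 were CMKLR1, the receptor of the adipokine chemerin, with a log2 fold change of 1.09 ± 0.17, and STC1, the secreted glycoprotein stanniocalcin, with 1.12 ± 0.22. SLC7A5, the large neutral amino acid transporter LAT1, had a log2 fold change of 0.76 ± 0.15 at a high level, 10.28 ± 0.05 against 9.52 ± 0.09 log2 units (SD, n = 3 per group). IRS2, an adaptor of the insulin receptor, had 0.95 ± 0.19, the methyltransferase gene TMT1B had 0.87 ± 0.18, and PRSS3, a trypsinogen with near-identical relatives, had 0.90 ± 0.19. Among the lower genes, ITGA6, the laminin-binding integrin alpha 6, had a log2 fold change of -1.36 ± 0.25 and CD164, a sialomucin, had -1.01 ± 0.18. MYH8, the perinatal myosin heavy chain, had -0.95 ± 0.16 and CALCOCO1, an autophagy receptor, had -0.84 ± 0.17. Their adjusted p over all probe sets ran from 0.169 for CMKLR1 to 0.437 for TMT1B and PRSS3.

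**Figure D1:**
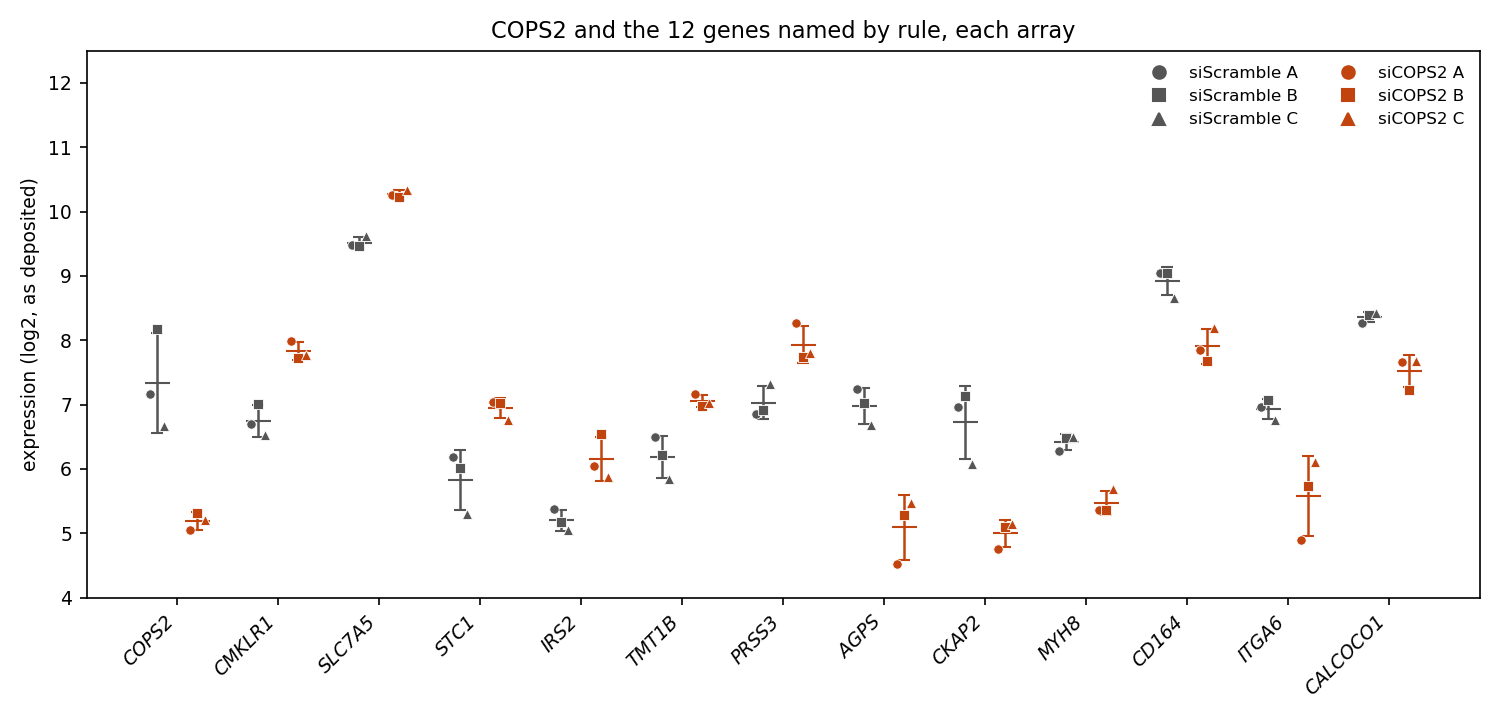
Deposited log2 expression of COPS2 and the 12 genes named by rule, 6 to the right of COPS2 that were higher after siCOPS2 and then 6 that were lower. Points are arrays (grey siScramble, orange siCOPS2, symbol shape for the letter), bars are the mean and SD of 3 arrays, and the groups do not overlap for any gene shown, as the rule requires; COPS2 averages 7.34 and 5.19 log2 units.

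In all, 0 of 21448 probe sets passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 1217 probe sets, 614 higher and 603 lower after siCOPS2, where 1072.4 would be met by chance. The other splits of the 6 arrays into 3 against 3 gave from 529 to 1721, so the real count lay within their range. The groups did not overlap for 2376 probe sets (11.1%), and chance gives 10% for 3 against 3. An absolute log2 fold change of at least 1 was reached by 13 probe sets. Leaving out siScramble B gave 1 call, COPS2, and leaving out siScramble C gave 2, CKAP2 and COPS2. Of the other unpaired fits, array weights gave 4 (COPS2, AGPS, CKAP2 and CMKLR1), a trended, robust variance 3 (AGPS, COPS2 and CKAP2) and quantile normalization again 2 (AGPS and COPS2), while median centring, the filter on dim probe sets and the restriction to probe sets with 1 symbol each gave 1, AGPS.

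Of the 32 gene lists, 4 passed camera's threshold with its preset correlation, and this count was 8 without siScramble B and 7 without siCOPS2 A. With an estimated correlation 0 passed, and 0 by fry's directional test. fry's mixed test, which asks whether the genes of a list change in either direction, passed for 3 lists: glucose uptake and insulin signalling (adjusted p = 0.034), endoplasmic reticulum stress and ATF4 (0.042) and myokines (0.042). Interferon response genes were higher after siCOPS2 as a group: 33 of 34 measured members had a higher mean and 1 a lower one (camera adjusted p = 7.11e-06). The adjusted p was 0.762 with an estimated correlation. The mean log2 fold change of the list was 0.41. IFIH1, a sensor of double-stranded RNA whose siScramble mean of 3.98 lies under the negative-control level of 4.16, had a log2 fold change of 0.82 ± 0.25, ISG20, an exonuclease, 0.45 ± 0.19, and the antiviral genes MX1 and OAS2 1.40 ± 0.67 and 0.85 ± 0.43. Of the members, 0 passed adjusted over the list alone and 0 over all probe sets in the unpaired fit. List scores were -0.27, -0.64 and 0.30 for siScramble A, B and C and 0.07, -0.27 and 0.81 for siCOPS2 A, B and C, so the groups overlapped (exact permutation p = 0.4, two-sided, unpaired), while the siCOPS2 array was the higher one within each letter. The call was lost without siCOPS2 C (adjusted p = 0.455) and without siScramble B (0.0501).

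Proliferation genes were lower as a group, with 32 of 40 members below and 8 above their siScramble mean (camera adjusted p = 1.17e-05; adjusted p = 0.558 with an estimated correlation). The members of smallest p were AURKA, a mitotic kinase, at a log2 fold change of -0.45 ± 0.15, KIF20A, a kinesin of cell division, at -0.67 ± 0.23, TOP2A, a DNA topoisomerase, at -0.86 ± 0.31, and CCNB1, cyclin B1, at -0.43 ± 0.17. Of the members, 0 passed adjusted over the list alone and 0 over all probe sets. The siScramble arrays spread from -0.12 to 0.34 in the list score and the siCOPS2 arrays from -0.16 to -0.09 (exact permutation p = 0.3, two-sided, unpaired). Within each letter the siCOPS2 array was the lower one, with differences of -0.24, -0.43 and -0.04 for A, B and C. The list kept its call whichever array was left out.

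Sarcomere and contraction genes were also lower as a group, with 33 of 43 members below and 10 above (camera adjusted p = 2.73e-04; adjusted p = 0.762 with an estimated correlation). MYH8 fell when adjusted over the list alone (limma adjusted p = 0.0028), from 6.42 ± 0.12 to 5.47 ± 0.19 log2 units (SD, n = 3 per group). It was the 1 member to pass there, and 0 passed over all probe sets. ANKRD1, a stretch-responsive ankyrin repeat protein, had a log2 fold change of -1.20 ± 0.32, LMOD3, a thin filament leiomodin, -0.87 ± 0.26, and MYOZ2, a Z-disc protein, -0.78 ± 0.24. List scores were 0.00, 0.04 and 0.27 for siScramble A, B and C. For siCOPS2 A, B and C they were -0.24, -0.20 and 0.13 (exact permutation p = 0.3, two-sided, unpaired). Within each letter the siCOPS2 array was the lower one, with differences of -0.24, -0.24 and -0.14 for A, B and C. Without siScramble C the adjusted p of the list was 0.249. With 1 array left out its mean log2 fold change ran from -0.33 to -0.13, against -0.21 with all 6.

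Endoplasmic reticulum stress and ATF4 genes were higher as a group, with 23 of 29 members above and 6 below (camera adjusted p = 2.73e-04; adjusted p = 0.558 with an estimated correlation). SLC7A5 and TRIB3, a pseudokinase induced in stressed cells, rose when adjusted over the list alone, at limma adjusted p of 0.0059 and 0.041, and 0 members passed over all probe sets. TRIB3 had a log2 fold change of 0.61 ± 0.16. CHAC1, which degrades glutathione, had 0.65 ± 0.19, and SLC3A2, the heavy chain that pairs with SLC7A5 in the transporter, had 0.46 ± 0.16. All 3 siCOPS2 arrays lay above all 3 siScramble arrays in the list score, the most extreme order that 3 against 3 can give (exact permutation p = 0.1, two-sided). The scores of the COP9, glycolysis, corepressor, myokine and satellite cell lists separated the groups as fully, with the same p. None of those is among the 4 lists past camera's threshold. The COP9 score includes COPS2, the target of the siRNA, so its separation is not independent of the knock-down. It was not scored without COPS2. The endoplasmic reticulum stress list kept its call whichever array was left out, with a highest adjusted p of 0.047 without siScramble A.

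**Figure D2:**
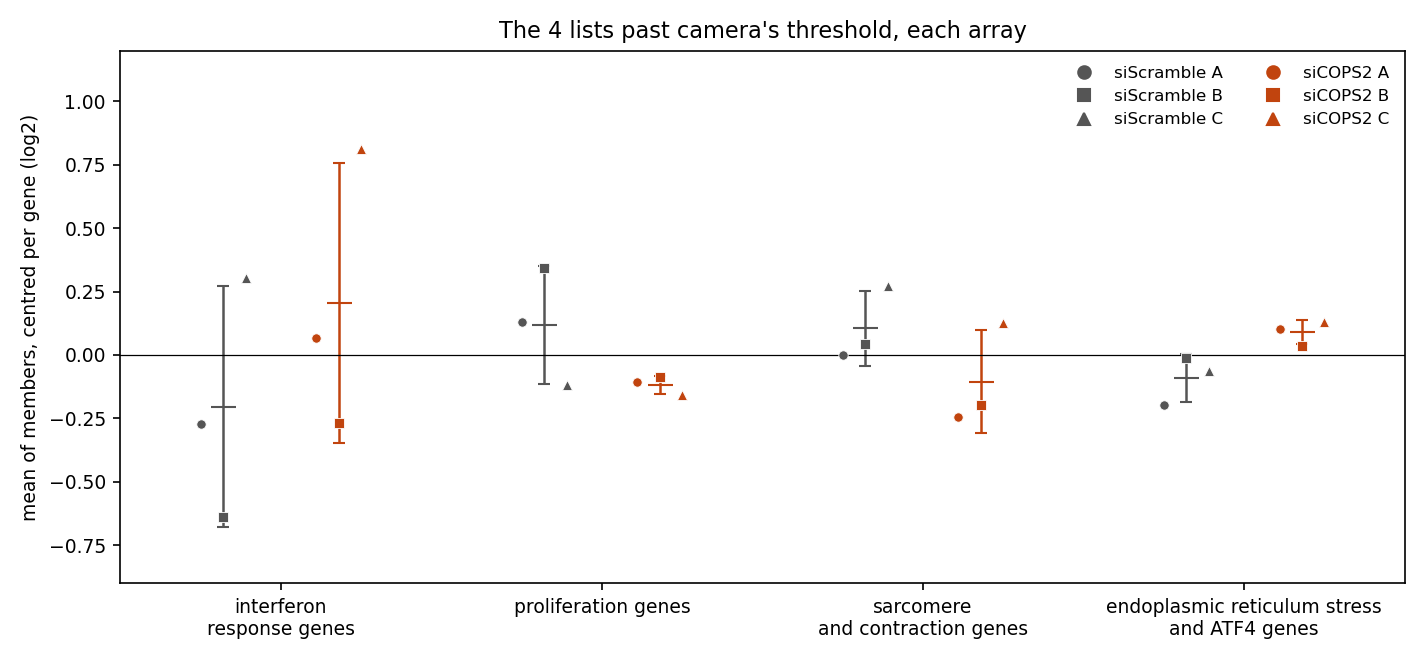
Per-array scores of the 4 gene lists past camera's threshold, as the mean over members of the log2 value minus that gene's mean over 6 arrays. Points are arrays, and bars are the mean and SD of 3 arrays; interferon scores run from -0.64 to 0.81 and overlap between the groups, while endoplasmic reticulum stress scores do not overlap.

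Of the COP9 signalosome, COPS2 was the 1 subunit to pass adjusted over the list alone, and 0 passed over all probe sets. In the list of 10 subunits, 4 were higher and 6 lower (camera adjusted p = 0.054; adjusted p = 0.558 with an estimated correlation), and with COPS2 left out, a test chosen after the data were seen, the adjusted p was 0.455. Among the unpaired fits the full list passed without siCOPS2 C (0.036), with quantile normalization again (0.028) and with a trended variance (0.04996). GPS1, or subunit 1, had a log2 fold change of 0.33 ± 0.15, COPS9 -0.33 ± 0.17 and COPS4 -0.29 ± 0.17. In the cullin-RING ligase and neddylation machinery, 18 members were higher and 18 lower (camera adjusted p = 0.303), with a mean below 0 and a median above it. Its members of smallest p were SKP2, an F-box protein, at -0.63 ± 0.20, CRBN, cereblon, at -0.55 ± 0.18, CAND2 at -0.61 ± 0.21 and RNF7, a RING subunit, at -0.50 ± 0.17. The 26S proteasome list had 18 higher and 12 lower (adjusted p = 0.694, and 0.041 without siScramble B; adjusted p = 0.989 with an estimated correlation and all 6 arrays) and the eIF3 list 5 higher and 8 lower (adjusted p = 0.549). Of the members of these 3 lists, 0 passed adjusted over their list alone.

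Of the lists on oxidative stress and muscle metabolism, which the study's title raises, none passed camera's threshold in the main fit. That fit has all 6 arrays, default priors and no block or covariate. Glycolysis genes were at an adjusted p of 0.054, with 0.038 under a trended variance and 0.558 with an estimated correlation. Glucose uptake and insulin signalling genes (camera adjusted p = 0.352) passed fry's mixed test (adjusted p = 0.034). NRF2 and antioxidant genes had 14 higher and 18 lower (camera adjusted p = 0.694), with AKR1C2, an aldo-keto reductase, at a log2 fold change of -0.53 ± 0.17 and the cystine transporter gene SLC7A11 at 0.31 ± 0.15. Oxidative phosphorylation genes had 29 higher and 18 lower and fatty acid oxidation genes 19 higher and 12 lower, both at an adjusted p of 0.475. Muscle atrophy and autophagy genes had 11 higher and 13 lower (adjusted p = 0.549), with TRIM32, a muscle ubiquitin ligase, at -0.51 ± 0.17 and BNIP3, a mitophagy receptor, at 0.39 ± 0.15. Myogenic regulators had 7 higher and 15 lower (adjusted p = 0.471). MYF5, a myoblast transcription factor, was at 0.71 ± 0.22, and NCAM1, MEF2C and the fusion gene MYMK were at -0.57 ± 0.20, -0.68 ± 0.27 and -0.90 ± 0.40. Of the members of the NRF2, oxidative phosphorylation, fatty acid oxidation, atrophy and myogenic lists, 0 passed adjusted over their list alone.

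Excitation-contraction coupling and calcium handling genes went both ways, 13 higher and 13 lower (camera adjusted p = 0.971), with the mean below 0 and the median above it. CASQ2, a calsequestrin that binds calcium in the sarcoplasmic reticulum, rose when adjusted over the list alone (limma adjusted p = 0.029), from 6.84 to 7.66 log2 units, a log2 fold change of 0.82 ± 0.19. ORAI1, a calcium channel of the plasma membrane, had 0.53 ± 0.15, PVALB, parvalbumin, 0.39 ± 0.16 with both means under the negative-control level, and CKM, muscle creatine kinase, -0.85 ± 0.27.

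Markers of other cells that such a culture could hold did not pass the test. Satellite cell and myoblast markers had 10 higher and 6 lower (camera adjusted p = 0.223), and 7 of the 16 also belong to another list. Fibroblast markers had 10 higher and 6 lower, a direction that flips with quantile normalization, adipocyte markers 6 higher and 5 lower, and immune cell markers 7 higher and 6 lower, each at an adjusted p of 0.971. Endothelial and pericyte markers had 7 higher and 5 lower (adjusted p = 0.694), with CLDN5 at a log2 fold change of -0.72 ± 0.21. For the adipocyte, endothelial and immune lists the mean, the median and the test differ in sign.

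**Figure D3:**
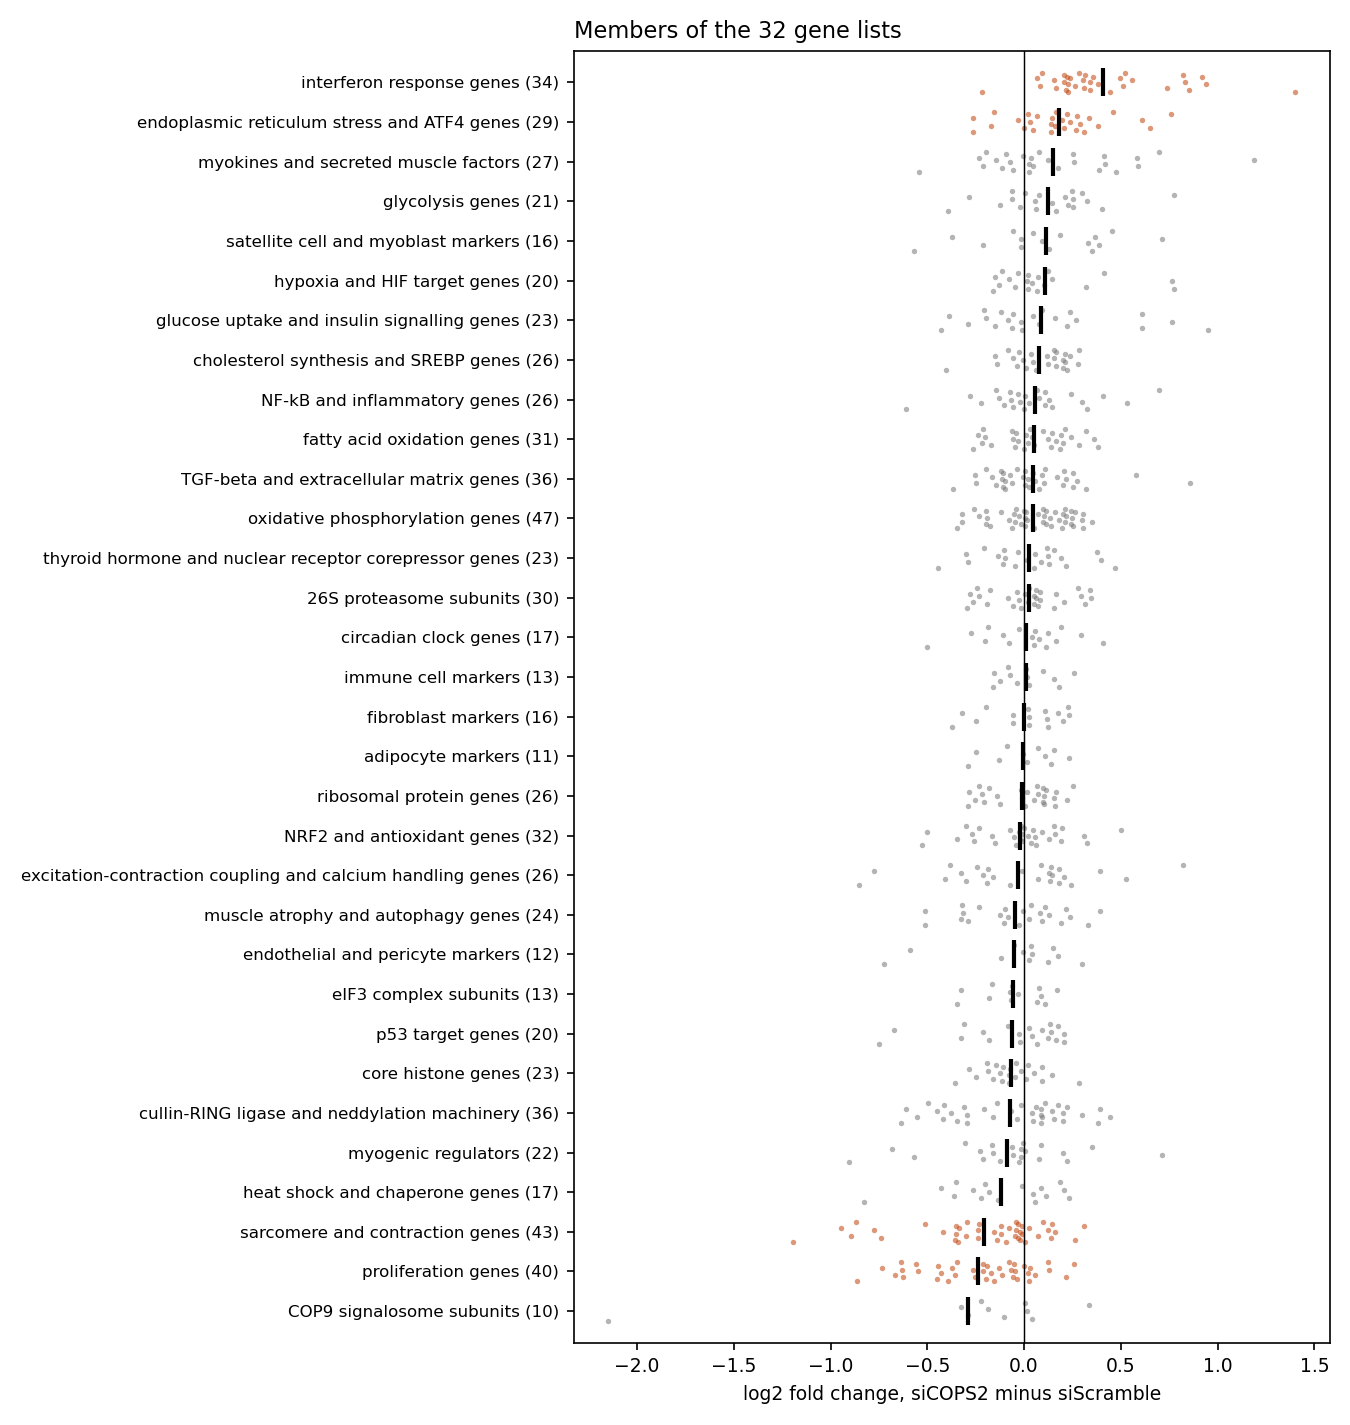
Log2 fold change (siCOPS2 minus siScramble) of every measured member of the 32 gene lists, with the number of measured members in brackets. Each point is 1 gene, black ticks are list means, and orange marks the 4 lists past camera's threshold; the mean of the interferon list is 0.41 and that of the proliferation list -0.24, while the COP9 mean of -0.29 includes COPS2 at -2.15.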

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

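The test of all deposited probe sets, controls included, the control-probe covariate and the COP9 list without COPS2 were chosen after the data were seen. The 0 probe sets past the threshold became 4 with the replicate block (COPS2, MX1 at an adjusted p of 0.0094, AGPS and CKAP2), 3 with trend and robust variance (AGPS, COPS2 and CKAP2), 4 with array weights (COPS2, AGPS, CKAP2 and CMKLR1), 2 with quantile normalization again (AGPS and COPS2) and 1, AGPS, with arrays centred on the median, with the filter on dim probe sets or with only probe sets with 1 symbol. It was 1217 at an unadjusted p under 0.05 and between 0 and 2 with an array left out, and stayed at 0 under every other alternative, ordinary variance, the random effect and both stricter thresholds included. The share of calls higher has no value with 0 calls. COPS2 was lower throughout: its log2 fold change passed the threshold with the replicate block (-2.15, adjusted p = 0.0049), trend and robust variance (-2.15, 0.030), array weights (-2.06, 0.0060) and quantile normalization (-2.13, 0.042). With an array left out it ran from -2.48 to -1.73, and its adjusted p over all alternatives ran from 0.0049 to 0.889, the highest with ordinary variance. The labels do not say that the letters pair the samples, so the fit without the block was fixed beforehand as the main one. Over all probe sets, deviations of same-letter arrays correlated at 0.039, 0.042 and 0.044 for A, B and C. No siScramble array correlated best with the siCOPS2 array of its own letter. In the interferon list, the only list checked in this way, each siScramble array did correlate best with its own letter. The same-letter correlations there were 0.35, 0.66 and 0.69. Letter C also had the highest score of both groups in the excitation-contraction list (0.28 in siScramble, 0.23 in siCOPS2). A level shared within letters may therefore not be confined to interferon genes. With the replicate block 6 lists passed camera's threshold, the 4 and those of COP9 subunits and myokines (both at an adjusted p of 0.0387). The 4 lists became 7 with trend variance (COP9 subunits, glycolysis and myokines added), 5 with quantile normalization (COP9 added), 7 with the control covariate (glycolysis, hypoxia and myokines added), 0 with an estimated correlation, 0 by fry's directional test, and 3 to 8 with an array left out; the 4 themselves passed in every full-array camera fit with the preset correlation and on ranks. camera was not run with the random effect, for which it has no setting, and its variance could be given a trend but not made robust. The cause of these changes was not tested; the median standard error of 0.17 and the probe sets under the negative-control level limit what 6 arrays can show.

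Every change of sign was of a result that passed under neither setting. The test of the ribosomal protein list turned up with trend variance (adjusted p = 0.984), array weights (0.438), the control covariate (0.454) and ranks (0.994). Array weights turned the excitation-contraction and NRF2 lists (both 0.929), and fry the former (0.994). Quantile normalization turned the TGF-beta (0.990) and fibroblast (0.764) lists, the dim filter the clock and endothelial lists (both 0.984), the covariate the eIF3 (0.801) and clock (0.923) lists, and the replicate block the immune list (0.970). With an array left out, these lists changed direction at least once, with adjusted p from 0.041 to 0.992 for 26S proteasome, 0.480 to 0.992 for fibroblast, 0.771 to 0.992 for adipocyte, 0.365 to 0.987 for immune, 0.123 to 0.731 for excitation-contraction, 0.176 to 0.992 for ribosomal protein, 0.716 to 0.992 for clock, 0.056 to 0.771 for cullin, 0.181 to 0.722 for eIF3, 0.291 to 0.992 for NRF2, 0.041 to 0.992 for TGF-beta, 0.174 to 0.987 for NF-kB and 0.018 to 0.794 for histone genes. So did EIF3D (log2 fold change from -0.319 to 0.051), RPS15 (from -0.0029 to 0.436) and CD68 (from -0.056 to 0.575). The other genes taken by rule kept their sign under every alternative run.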

Other observations

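The tests of the interferon list and the test of cycling cells were chosen after the results were seen, as were the adjustment over all list genes together and the count of splits for each list. Some genes passed adjusted over a list alone in lists whose camera test with the preset correlation did not pass in the main fit of all 6 arrays. In the glucose uptake and insulin signalling list, IRS2, the glucose transporter gene SLC2A1, TRIB3 and RPTOR, the raptor subunit of mTORC1, rose when adjusted over the list alone (limma adjusted p = 0.0064, 0.0083, 0.022 and 0.049). The list had 11 higher and 12 lower, its mean above 0 and its median below (camera adjusted p = 0.352). PDK1, a kinase that restrains pyruvate dehydrogenase, rose by the same count in the glycolysis list (0.036), which had 15 higher and 6 lower (camera adjusted p = 0.054), and with SLC2A1 in the hypoxia list, which had 13 higher and 7 lower (camera adjusted p = 0.234). Without siScramble B the adjusted p was 0.043 for glycolysis, 0.012 for hypoxia and 0.041 for the myokine list, and without siCOPS2 A it was 0.047 for glycolysis and myokines. With all 6 arrays, camera's adjusted p was 0.038 for glycolysis and myokines under a trended variance, and 0.0387 for myokines with the replicate block. With the control covariate it was 0.042 for glycolysis and myokines and 0.021 for hypoxia. With an estimated correlation and all 6 arrays the adjusted p was 0.558 for glycolysis, 0.838 for hypoxia and 0.558 for myokines. Log2 fold changes were 0.76 ± 0.17 for SLC2A1, 0.78 ± 0.19 for PDK1 and 0.61 ± 0.19 for RPTOR. Among myokines, 17 higher and 10 lower (camera adjusted p = 0.054), the growth factor gene NRG1 and the cytokine gene LIF rose when adjusted over the list alone, both at 0.015, with log2 fold changes of 1.19 ± 0.27 and 0.70 ± 0.16. IGFBP3 and IGFBP5, which bind insulin-like growth factors, were both at 0.59, with standard errors of 0.19 and 0.20. ZMAT3, an RNA-binding p53 target, fell when adjusted over its list alone (0.047), at -0.75 ± 0.20, while p53 targets had 11 higher and 9 lower (camera adjusted p = 0.549), the mean below 0 and the median above.

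In all, 12 genes from 10 lists passed adjusted over a list alone. Adjusted over the 756 list genes together, 2 passed: COPS2 (0.0062) and MYH8 (0.024), with SLC7A5 at 0.051 and IRS2 at 0.052. LIF also passed in the list of NF-kB and inflammatory genes, 14 higher and 12 lower (camera adjusted p = 0.491). TGF-beta and extracellular matrix genes had 20 higher and 16 lower (0.549, and 0.041 without siScramble B), a direction that flips with quantile normalization, with CCN2 at a log2 fold change of 0.58 ± 0.15 and TIMP3 at 0.86 ± 0.24. Cholesterol synthesis genes had 18 higher and 8 lower (0.232), heat shock genes 7 higher and 10 lower (0.292, and 0.015 without siCOPS2 C) and core histone genes 7 higher and 16 lower (0.323, and 0.018 without siCOPS2 A). With an estimated correlation and all 6 arrays the adjusted p was 0.893 for the TGF-beta list and 0.838 for the heat shock and histone lists. Thyroid hormone and corepressor genes, which concern COPS2 as a corepressor, had 13 higher and 10 lower (0.694). Clock genes had 10 higher and 7 lower and ribosomal protein genes 15 higher and 11 lower with the mean below 0, both at 0.971.

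The 6 arrays make 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 0 probe sets, so that all 10 give as many by construction and the count says nothing about chance; the highest of the others was also 0. For gene lists, 7 of 10 splits gave as many as the real one, which gave 4, and the highest of the others gave 10. That split put siScramble A, siCOPS2 A and siCOPS2 B against the rest, so it is not independent of the siRNA; what gave it more lists than the real split was not tested. The interferon list passed in 7 of the 10 splits, the real one included, with a smaller adjusted p than the real 7.11e-06 in 4 others, down to 1.18e-22. The sarcomere list passed in 5 and was smaller than the real 2.73e-04 in 2 others, down to 3.44e-10, and the proliferation list passed in 4 and was smaller than the real 1.17e-05 in 1 other, at 1.76e-06. The endoplasmic reticulum stress list passed in 2, and its real adjusted p of 2.73e-04 was the smallest of the 10, with 0.0054 the next.

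The interferon list was higher in siCOPS2 arrays. Whether a single array may carry the difference was left open: without siCOPS2 C the mean log2 difference was 0.10 against the full 0.41, but that leaves siScramble C, the highest control, and without both C arrays it was 0.36. The siCOPS2 array was above the siScramble array within each letter, by 0.34, 0.37 and 0.51 for A, B and C; this decides nothing about a level shared by arrays of one letter, which by design enters both groups alike. Arrays of a letter did deviate together in these genes, with correlations across genes of 0.35, 0.66 and 0.69 for A, B and C. Transfected RNA can induce these genes, so a difference between the 2 siRNAs in that property, apart from COPS2, stays open and was not tested.

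The sarcomere and proliferation lists were both lower in siCOPS2 arrays. More cycling, undifferentiated cells would lower the first and raise the second. The proliferation list was at -0.12 at the highest with an array left out. Its difference of -0.24 was within 2 standard errors (0.14 each), so this account cannot be told apart from others. The satellite cell and myoblast list, which also marks undifferentiated cells, had a mean difference of 0.11, with 10 members higher and 6 lower. It did not pass (camera adjusted p = 0.223), so it does not settle the account either. Array quality, measured by how well positive controls stood apart from negative ones, may also contribute. With that measure as a covariate the mean differences were -0.20 ± 0.18 for the sarcomere list and -0.17 ± 0.12 for the proliferation list (SE), against -0.21 and -0.24 without it, too uncertain to exclude it. A response of the cells to the loss of COPS2 stays open as well.

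AGPS and CKAP2 were nearly as far down as COPS2. A single array does not account for this, since the smaller of the 2 differences with any array left out was still -1.52. Because an siRNA can silence other transcripts through a short seed match, an off-target effect is a candidate explanation beside a response to COPS2 loss; the siRNA sequences are not given in the sources used here, and this was not tested.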
